A study of Homo sapiens with 12 samples.

How the data were processed

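RNA-seq of poly(A) RNA was available for 12 libraries in 5 groups from 2 human cell lines: BICR31 with siKLF5 or siNC (3 libraries each) and HCC95 with an empty vector, KLF5 WT or KLF5 E419Q (2 libraries each). Groups and replicate letters were taken from the labels. RNA was extracted with RNeasy columns, poly(A) RNA selected and libraries made with NEB kits, per the labels' protocols. The siRNA sequence, the vector and the time of harvest are not given in the sources used here.

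Reads were aligned with STAR and counted per gene with RSEM against hg19, per the submitters' processing notes, which give no versions. For HCC95 the notes also name edgeR and limma. The HCC95 files hold RSEM expected counts, which the authors deposited unscaled per gene, and beside them TPM and FPKM columns that the authors deposited as RSEM wrote them, per the file headers. TPM and FPKM were not used for any test, and the deposited gene lengths served only to check for a length trend. The BICR31 files hold a deposited signal named as normalised, and how the authors made it is not given in the sources used here. From the values, the 75th percentile of the signal above 0 lay at 983 to 992 in each library, as upper-quartile scaling to a common value would leave it. The first line of each BICR31 file, a header turned into a number, was left out.

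In the BICR31 files 1 count was worth 7.87 to 9.12 units, and dividing by that step made 81.4% to 82.6% of the values above 0 whole within 0.02. The counts per BICR31 library given in the report come from this step and are estimates. A level of 3 counts equals 1.31 to 1.56 CPM in BICR31 and 0.646 to 0.976 CPM in HCC95, where CPM is the count relative to the library's total, scaled as usual. Mitochondrially encoded genes took 1.63% to 2.61% of counts in BICR31 and 2.74% to 3.02% in HCC95, and the 10 most abundant genes 4.13% to 7.41%. Each file listed 57820 gene IDs, which the HCC95 files pair with symbols. Biotypes came from GENCODE 29, matched by ID for 52338 of them (19263 protein-coding). That annotation is of a later build than hg19, so no coordinates are given. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.23 to 1.83 within groups, 5.40 to 9.13 between groups), so none was counted once.

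In BICR31, log2(signal + 1) of 15710 genes with a mean of at least 10 units was tested with limma (version 3.58.1, empirical Bayes with a mean-variance trend). In HCC95, expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood method (version 4.0.16, TMM scaling, filterByExpr, 12933 genes), with all 6 libraries in the fit. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels in HCC95 are CPM. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation and with fry. With an estimated correlation camera's p also rests on the few residual degrees of freedom of the fit. A call lost there can therefore reflect the few libraries rather than correlation of the members. Calls shared by the cell lines were counted with Fisher's exact test. Computations ran in R 4.3.3 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

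Genes named were KLF5, and in each comparison the 8 largest rises and falls among protein-coding genes with an adjusted p under 0.05, no overlap of the groups' libraries, and a mean of at least 100 units or 5 CPM in the higher group. Named too were up to 3 members per list with the smallest adjusted p, and 8 genes lowered by siKLF5 and raised by WT with the largest summed change. Members of lists too short to test are also named. The 32 lists, some of which share genes, were basal squamous cell, squamous differentiation, stress keratins and alarmins, squamous transcription factors, epithelial junctions, mesenchymal, G1/S and G2/M cell cycle, interferon response, NF-kB and inflammatory cytokines, EGFR ligands and receptors, MAPK early response and feedback, KLF and SP factors, literature KLF5 targets, p53 targets, cholesterol synthesis, glycolysis and hypoxia, ATF4 and unfolded protein response, heat shock, TGF-beta targets, YAP/TEAD targets, WNT targets, NOTCH pathway, NRF2 targets, intestinal epithelium, lung lineage, ribosome biogenesis and MYC, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and other cell types (fibroblast, endothelial, immune).

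Tests were checked on libraries simulated from real means and library sizes with 200 genes changed. Of changes of 1.5, 2 and 4-fold, 41.8%, 46.3% and 63.6% were called for siKLF5 against siNC (15387 genes), 56.7%, 68.7% and 98.5% for WT against the empty vector (12726 genes), 52.2%, 83.6% and 92.4% for E419Q against the empty vector (12722 genes), and 56.7%, 70.1% and 93.9% for E419Q against WT (12696 genes). Of all calls, 5.61%, 7.45%, 8.43% and 5.16% were false, in that order. Camera called a set of changed genes and 0 of 50 random sets, which cannot test false calls of correlated lists.

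Alternatives were other pseudocounts, filters, scalings and thresholds, limma without a trend, DESeq2 (version 1.42.0), limma-voom, fits of only the groups compared, the replicate letter as a block, and each library left out in turn. Alternatives added after the data were seen were edgeR on counts recovered from the BICR31 steps, an overlap within classes of mean expression, libraries thinned to the lowest total, and removal of a length trend.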

Results

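Gene expression was measured by RNA-seq of poly(A) RNA in 2 human squamous carcinoma cell lines in which the level of the transcription factor KLF5, a zinc-finger protein of epithelial cells, had been altered. BICR31, a line from a head and neck squamous cell carcinoma, was treated with a small interfering RNA against KLF5 (siKLF5, 3 libraries) or with the siNC control (3 libraries). HCC95, a lung squamous cell carcinoma line, carried an empty vector, a vector for wild-type KLF5 (WT) or a vector for the missense form E419Q (2 libraries each). The residue changed in E419Q lies in the DNA-binding part of the protein. The comparisons ask what silencing of KLF5 changes, what its overexpression changes, and whether E419Q acts on other genes than WT. The files held 2150790 to 2296190 assigned counts per siKLF5 library and 1922360 to 1934350 per siNC library. In HCC95 they held 3455400 to 4643790 counts with the empty vector, 3516980 to 3992550 with WT and 3074140 to 3364760 with E419Q. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

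KLF5 itself (ENSG00000102554.9) was measured first, as a check of the labels. In BICR31 its level was 958.7 ± 67.5 units of the deposited normalised signal (SD, n = 3) with siKLF5 against 2530 ± 211 units (n = 3) with siNC, that is 37.9% of the control. This fall had a log2 fold change of -1.40 (SE 0.0926, limma adjusted p = 7.27e-09), and every siKLF5 library (882 to 1008 units) lay under every siNC library (2289 to 2682 units). In HCC95 KLF5 stood at 145.1 ± 9.92 CPM (counts relative to the library's total, n = 2) with the empty vector, 414.6 ± 11.99 CPM with WT and 431.8 ± 9.56 CPM with E419Q. It rose by a log2 fold change of 1.52 with WT (SE 0.0677, edgeR adjusted p = 5.46e-13) and 1.58 with E419Q (SE 0.0681, edgeR adjusted p = 1.17e-13). Between E419Q and WT the KLF5 transcript showed no detectable difference at this depth: the fold was 1.04 (95% interval 0.910 to 1.19, edgeR adjusted p = 0.683).

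**Figure D1:**
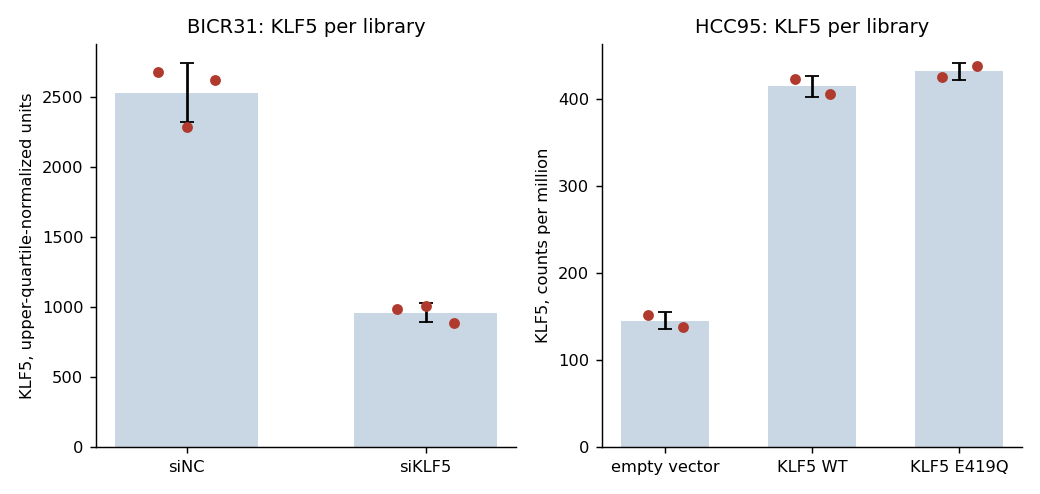
KLF5 level per library (points), with group mean (bar) and SD (line): normalised units in BICR31 on the left, CPM in HCC95 on the right, both axes from 0. The siKLF5 libraries lie between 882 and 1008 units against 2289 to 2682 units with siNC, and the HCC95 libraries lie at 138 to 152 CPM with the empty vector, 406 to 423 CPM with WT and 425 to 439 CPM with E419Q.

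Silencing of KLF5 in BICR31 was followed by higher levels of inflammatory cytokine, interferon response and epithelial junction genes and by lower levels of DNA replication, ribosome biogenesis and basal squamous genes. Among the largest rises were IDO1, an interferon-induced enzyme (58 counts against 2, 25.98-fold, 95% counting interval 6.88 to 219.7), and SERPINA3, an acute-phase protease inhibitor, which rose 26.7-fold (1479 ± 217 against 59.7 ± 28.3 units, limma adjusted p = 4.89e-09). KRT23 rose 23.95-fold (3763 ± 349 against 157 ± 28.5 units, limma adjusted p = 1.45e-12). Values in parentheses after a gene symbol are log2 fold changes, and those after a library left out are the adjusted p without it. Other large rises were those of ATG9B (4.31), KCNK15 (4.23), ADAMTS9 (4.18), CFTR (4.17), an epithelial chloride channel and PGBD5 (3.98). Among the largest falls, KRT4 (-2.80), a keratin of the oral and oesophageal mucosa, fell (227 ± 80.9 against 1504 ± 70.8 units, limma adjusted p = 4.21e-08), and TGM1 (-2.59), the transglutaminase of the cornified envelope, and OVOL2 (-2.25), a repressor of mesenchymal genes, fell too. ALPP (-2.47), an alkaline phosphatase with close paralogs, SDPR (-2.36) and PSAPL1 (-2.26) were also among the 8 largest falls. FEM1A (-3.68) was uneven, at 147 ± 169 against 423 ± 42.6 units (limma adjusted p = 0.0466), and lost its call without siKLF5 C (0.0692), siNC A (0.111), siNC B (0.113) and siNC C (0.134). The call of RP11-298I3.5 (-3.55) was lost without siNC A (0.0841) and siNC C (0.1002).

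Of 15710 genes tested with limma in BICR31, 2404 rose and 1693 fell (26.1% changed; 568 and 193 with at least a 2-fold change), and 5710 had an unadjusted p under 0.05. Raised genes made up 58.7% of calls, but 48.5% (2005 up, 2129 down) with quantile-normalised values. Counts of 2-fold changes use log2(value + 1), which can understate changes of low genes and overstate uneven ones like FEM1A's.

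Medians and means of gene lists are of the log2 fold changes of their tested members, and the p-value after a median is camera's. Where no other count is given, the count adjusted over the list alone was the same as that over all genes tested. A range in parentheses after a count of members is that with single libraries left out, given where it moves the count by over 1.5 times. Among 32 gene lists fixed before the data were examined, 18 passed camera's test at its preset correlation in BICR31, 9 upward and 9 downward, and 7 of them also with the correlation estimated from the data. Genes of NF-kB signalling and inflammatory cytokines had the largest mean change of the lists (mean 1.54, median 1.42, adjusted p = 4.65e-15, adjusted p = 0.0337 with an estimated correlation). Of 24 members 22 rose, or 22 rose and 1 fell adjusted over the list alone. PTGS2, the inducible cyclooxygenase, rose to 2406 ± 171 against 272 ± 8.26 units (3.14, limma adjusted p = 5.84e-12), and LIF (1.44), a cytokine, and NFKBIA (0.98), the feedback inhibitor of NF-kB, rose as well. Interferon response genes rose (median 0.54, adjusted p = 2.62e-05, adjusted p = 0.0337 with an estimated correlation), with the smallest p-values for CXCL10 (3.63), a chemokine at 705 ± 176 against 60.5 ± 29.1 units, the antiviral GTPase MX2 (1.80) and the RNA sensor DDX58 (1.39). Of 25 members 12 rose, or 14 adjusted over the list alone. Epithelial junction genes rose (median 0.36, adjusted p = 3.01e-07, adjusted p = 0.0302 with an estimated correlation), with the claudins CLDN4 (1.19) and CLDN1 (1.40) and the adherens junction cadherin CDH1 (0.81) as examples. Of 25 members 15 rose and 2 (1 to 2) fell. Markers of fibroblasts, endothelium and immune cells, measured because such cells could be present, did not pass as a list but moved with the inflammatory genes (median 0.80, adjusted p = 0.0610). Of 8 members 3 rose, or 4 adjusted over the list alone. They were COL6A1 (1.19), a collagen chain, CD68 (0.97), a lysosomal protein of macrophages and other cells, and VWF (1.21), which lost its call without siKLF5 A (0.133), siKLF5 C (0.0501) and siNC C (0.0749).

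Genes of proliferation and growth fell. G1/S genes fell as a list (median -0.57, adjusted p = 1.11e-18, adjusted p = 0.0302 with an estimated correlation). Of 26 members 24 fell. Among them were MCM2 (-0.79) and MCM4 (-0.75), parts of the replicative helicase, and TYMS (-0.66), thymidylate synthase. G2/M genes fell as well (median -0.27, adjusted p = 4.71e-08, adjusted p = 0.0302 with an estimated correlation), such as CDC20 (-0.52) and PLK1 (-0.41) of mitosis and the transcription factor MYBL2 (-0.38). Of 26 members 16 fell, or 18 adjusted over the list alone. Ribosome biogenesis and MYC genes fell (median -0.57, adjusted p = 3.48e-14, adjusted p = 0.0302 with an estimated correlation), including the nucleolar proteins NPM1 (-0.58), FBL (-1.46) and DKC1 (-0.73). Of 20 members 16 fell, or 17 adjusted over the list alone. Basal squamous genes also fell (median -0.55, adjusted p = 9.72e-08, adjusted p = 0.0331 with an estimated correlation). Of 20 members 3 rose and 12 fell, or 3 and 13 adjusted over the list alone. Here the basal keratin KRT5 (-0.62) and the hemidesmosome integrin ITGB4 (-1.25) fell while CDH3 (0.76), placental cadherin, rose.

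The calls of 11 further lists in BICR31 did not hold with an estimated correlation. Limma's fry, which tests a list by itself, called 27 lists, among them all of these but the mitochondrially encoded genes. Mesenchymal genes rose (median 0.50, adjusted p = 0.00343, adjusted p = 0.103 with an estimated correlation), such as fibronectin, FN1 (1.12), and the collagen chains COL1A1 (1.13) and COL1A2 (1.34). Of 16 members 9 rose and 1 fell. Cholesterol synthesis genes rose (median 0.35, adjusted p = 5.61e-05, adjusted p = 0.234 with an estimated correlation), among them HMGCS1 (1.03) and DHCR7 (0.44), enzymes of the pathway. Of 23 members 12 rose and 1 (0 to 1) fell, or 15 and 2 adjusted over the list alone. Ribosomal proteins (median -0.14, adjusted p = 1.39e-06, adjusted p = 0.293 with an estimated correlation) fell slightly, with RPS2 (-0.39) and RPLP0 (-0.39). Of 28 members 1 (0 to 1) rose and 14 fell, or 1 and 15 adjusted over the list alone. Heat shock genes fell as a list (median -0.31, adjusted p = 0.00139, adjusted p = 0.0816 with an estimated correlation): the chaperones HSPA8 (-0.39) and HSPD1 (-0.47) fell while HSP90AA1 (0.28) rose. Of 13 members 3 rose and 8 fell. Nuclear genes of oxidative phosphorylation (median -0.12, adjusted p = 0.00280, adjusted p = 0.103 with an estimated correlation) fell, such as CYC1 (-0.37) and UQCRC1 (-0.43) of respiratory complex III. Of 25 members 5 (3 to 5) fell, or 4 adjusted over the list alone. YAP/TEAD targets fell (median -0.14, adjusted p = 0.0126, adjusted p = 0.114 with an estimated correlation), with the junction protein AJUBA (-1.10) and the receptor kinase AXL (-1.38) down and the phosphatase PTPN14 (0.80) up. Of 17 members 1 rose and 4 fell.

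Squamous transcription factors rose as a list (median 0.31, adjusted p = 0.0344, adjusted p = 0.456 with an estimated correlation), although FOSL1 (-1.23) of the AP-1 family fell while the epithelial factor ELF3 (0.81) and HES2 (1.03) rose. The list lost its call without siNC B (0.101). Of 23 members 10 rose and 4 fell, or 11 and 5 adjusted over the list alone. Histone genes (median 0.78, adjusted p = 0.0344, adjusted p = 0.177 with an estimated correlation) rose, with HIST1H2BK (0.61) among them, and lost the call without siKLF5 A (0.0604). Of 10 members 3 (1 to 3) rose, or 5 adjusted over the list alone. ATF4 and unfolded protein response genes (median 0.36, adjusted p = 0.0483, adjusted p = 0.283 with an estimated correlation) rose, such as the endoplasmic reticulum proteins PDIA4 (1.09) and HSPA5 (0.45), while the amino acid transporter subunit SLC3A2 (-0.56) fell. The list's call was lost without siKLF5 A (0.0760), siKLF5 C (0.0685) and siNC B (0.0597). Of 22 members 9 rose and 3 fell. TGF-beta targets rose (median 0.31, adjusted p = 0.0483, adjusted p = 0.283 with an estimated correlation), with ID3 (1.25) and BHLHE40 (0.59) up and ID1 (-0.85) down. This list lost its call without siKLF5 A (0.0760), siKLF5 B (0.0872) and siNC A (0.0580). Of 16 members 8 (4 to 7) rose and 2 (1 to 2) fell, or 10 and 2 adjusted over the list alone. Mitochondrially encoded genes fell (median -0.14, adjusted p = 0.0493, adjusted p = 0.623 with an estimated correlation), and MT-ND4L (-0.68) was the gene called. Of 13 members 1 (1 to 4) fell. Leaving out siKLF5 A turned this list's direction, and its call was lost without siKLF5 A (0.672), siNC B (0.189) and siNC C (0.0667).

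The remaining lists did not pass camera's test in BICR31, yet held genes that changed. Squamous differentiation genes were mixed (median 0.36, adjusted p = 0.0738), with the peptidase KLK7 (2.05) up and KRT4 and TGM1 down. Of 22 members 10 rose and 3 fell, or 10 and 4 adjusted over the list alone. Stress keratins and alarmins (median 1.43, adjusted p = 0.140) parted too: KRT6A (-1.37), a keratin of wound edges with close paralogs, fell, and the alarmin S100A9 (2.61) and LCN2 (1.51), lipocalin, rose. Of 10 members 4 rose and 1 fell. The EGFR ligands and receptors (median 0.28, adjusted p = 0.111) held the receptor ERBB3 (1.16) and the ligand EREG (0.49). Of 11 members 4 (2 to 4) rose, or 5 adjusted over the list alone. MAPK early response genes (median 0.23, adjusted p = 0.460) held IER3 (0.80) and DUSP5 (0.83), an ERK phosphatase. Of 20 members 7 rose and 4 (2 to 4) fell. KLF and SP factors (median 0.16, adjusted p = 0.489) included the paralogs KLF6 (0.90), KLF4 (0.90) and KLF12 (0.79) among the raised genes. Of 17 members 3 rose and 2 (0 to 3) fell, or 3 and 3 adjusted over the list alone. Literature KLF5 targets went both ways (median -0.10, adjusted p = 0.808, mean 0.10, a downward test): the cell cycle inhibitors CDKN1A (1.47) and CDKN2B (1.61) rose and cyclin D1, CCND1 (-0.43), fell. Of 13 members 5 rose and 5 fell. Among p53 targets (median 0.28, adjusted p = 0.235) TP53INP1 (2.21) rose and RRM2B (-1.11) fell. Of 21 members 8 rose and 4 fell, or 10 and 4 adjusted over the list alone.

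Glycolysis and hypoxia genes were balanced (median 0.03, adjusted p = 0.991, mean 0.13, a downward test), with PGK1 (-1.44) down and hexokinase, HK2 (0.65), up. Of 20 members 3 rose and 3 fell. In the WNT targets (median -0.20, adjusted p = 0.634) DKK1 (0.72) rose and APCDD1 (-1.73) fell. Of 13 members 2 (1 to 2) rose and 1 fell. NOTCH pathway genes (median 0.34, adjusted p = 0.425) included the ligand JAG1 (1.45), which rose, and the feedback regulator NRARP (-1.93), which fell. Of 11 members 5 rose and 3 fell, or 5 and 4 adjusted over the list alone. NRF2 targets (median -0.04, adjusted p = 0.814) held TXNRD1 (0.32), thioredoxin reductase. Of 21 members 3 rose, or 2 adjusted over the list alone. For intestinal epithelium genes (median -0.14, adjusted p = 0.0796) the simple-epithelium keratins KRT8 (-0.75) and KRT18 (-0.73) fell. Of 8 members 1 (0 to 2) rose and 2 fell, or 2 and 2 adjusted over the list alone. The lung lineage list (median -0.03, adjusted p = 0.762, an upward test) held 1 called gene, FOXA1 (0.65), a pioneer factor of endodermal tissues. Of 5 members 1 rose.

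**Figure D2:**
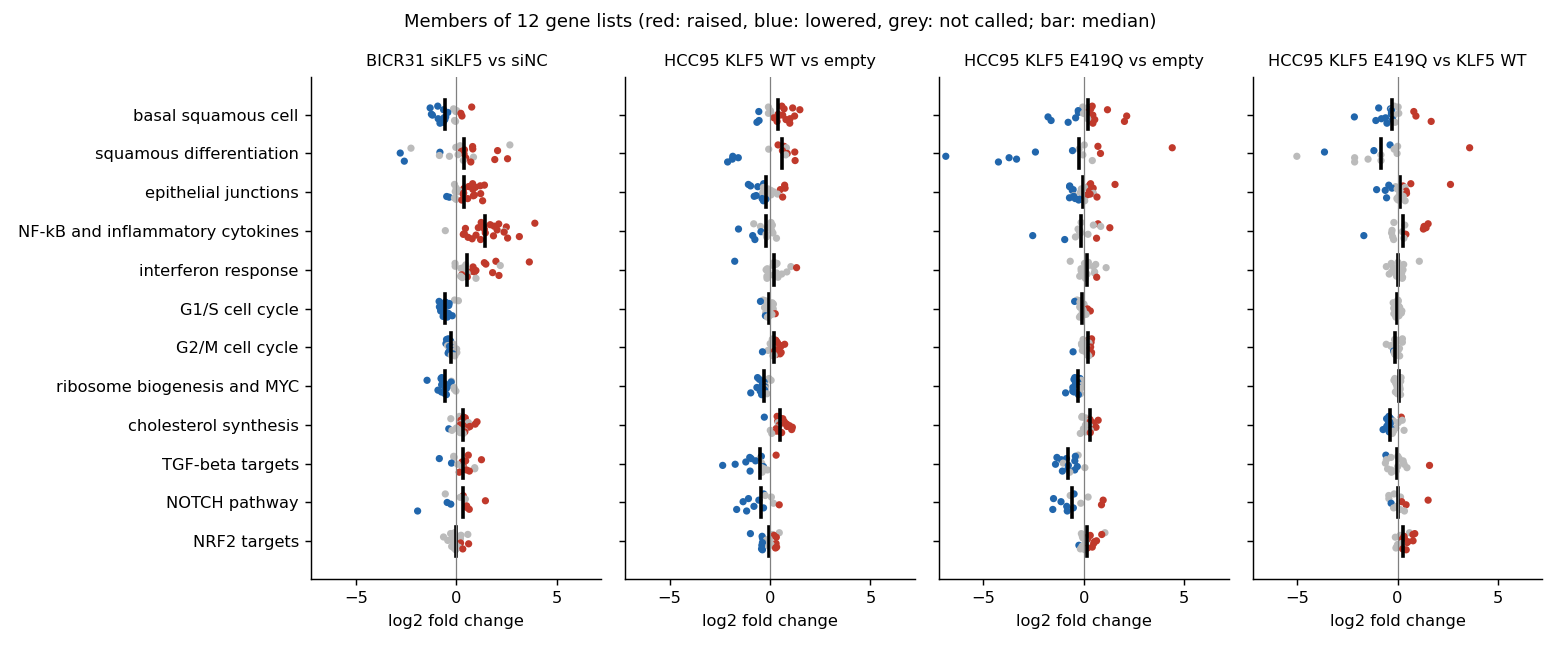
Log2 fold changes (horizontal axis) of the members of 12 gene lists in the 4 comparisons; each point is a gene, red where raised, blue where lowered and grey where not called, and the black bar is the list's median. The inflammatory cytokine list has its median at 1.42 with siKLF5, and the ribosome biogenesis list has medians of -0.57, -0.32 and -0.30 in the comparisons with a control. Points of genes with 3 counts or fewer in a group are fitted values, not bounds.

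Wild-type KLF5 in HCC95 was followed by higher levels of basal squamous, cholesterol synthesis and mitotic genes and lower levels of ribosome biogenesis, TGF-beta, NOTCH and YAP/TEAD genes, as list calls that did not hold with an estimated correlation. The largest rises were those of SUSD2 (50 counts against 1, 53.5-fold, 95% counting interval 9.17 to 2155), MPPED1 (39 counts against 2, 20.9-fold, 95% counting interval 5.401 to 178) and SORCS2 (3.50). MFAP5 (3.50), ALPP (3.18) (9.08-fold, 14.1 ± 6.02 against 1.46 ± 0.405 CPM), LOXL4 (3.03) and IGFL1 (2.75) (6.72-fold) rose as well. TMEM110-MUSTN1 (2.81), a read-through of 2 neighbouring genes, lost its call without empty vector B (0.124) and WT B (0.192). Among the largest falls, MMP9 had 1 count against 98 (91.6-fold, 95% counting interval 16.1 to 3655) and MMP7 (-4.21) was 18.5-fold lower. OLFM4 (-5.18) fell 36.2-fold, CD274 (-3.46), the immune checkpoint ligand PD-L1, 10.99-fold, and IL7R (-3.29) 9.79-fold (12.5 ± 0.188 against 121 ± 16.4 CPM, edgeR adjusted p = 5.16e-13). IGFBP5 (-3.23) fell 9.35-fold. LGR5 (-3.38) was lower too, a call lost without empty vector A (0.0555). EIF3CL, a near-identical copy of the translation initiation factor gene EIF3C, had 3 counts against 1847 (575-fold, 95% counting interval 197 to 2793), and the counting could split reads between the copies. Counting intervals, and the floors used for groups with no counts, cover counting error only.

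Of 12933 genes tested with edgeR in HCC95, 1394 rose and 1568 fell with WT against the empty vector (22.9%; 274 and 171 by at least 2-fold). With DESeq2 511 rose and 626 fell. Without WT A the counts were 785 and 934, and without WT B 1025 genes fell. Of 29 lists with at least 5 members tested, 13 passed camera's test, 6 upward and 7 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.139), where 5 had an unadjusted p under 0.05; fry called 14.

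Basal squamous genes rose with WT (median 0.38, adjusted p = 8.31e-07, adjusted p = 0.247 with an estimated correlation), among them the keratin KRT15 (1.22), the hemidesmosome collagen COL17A1 (1.12) and the squamous master regulator TP63 (0.98). Of 20 members 13 rose and 3 fell. Cholesterol synthesis genes rose (median 0.48, adjusted p = 4.82e-14, adjusted p = 0.262 with an estimated correlation), with LSS (0.96), lanosterol synthase, and INSIG1 (0.83). Of 23 members 18 rose and 1 fell, or 20 and 1 adjusted over the list alone. Mitotic genes rose (median 0.22, adjusted p = 2.48e-05, adjusted p = 0.262 with an estimated correlation), such as the topoisomerase TOP2A (0.50), NUSAP1 (0.55) of the spindle and the kinetochore protein CENPF (0.48). Of 26 members 13 (8 to 13) rose and 1 (0 to 1) fell, or 14 and 1 adjusted over the list alone. Literature KLF5 targets rose (median 0.30, adjusted p = 0.00801, adjusted p = 0.247 with an estimated correlation), including FGFBP1 (1.37), which releases fibroblast growth factors, and FASN (0.35), fatty acid synthase. Of 12 members 7 (4 to 7) rose and 2 (1 to 2) fell. Ribosomal proteins rose slightly (median 0.17, adjusted p = 3.56e-06, adjusted p = 0.359 with an estimated correlation), such as RPL10A (0.29), RPL5 (0.27) and RPL13 (0.26). Of 28 members 16 (6 to 18) rose and 1 fell, or 19 and 1 adjusted over the list alone. Squamous differentiation genes were called upward (median 0.61, adjusted p = 0.0290, adjusted p = 0.279 with an estimated correlation), but their mean was -0.07: the mucosal keratins KRT13 (0.61) and KRT4 (1.23) and the envelope protein PPL (0.85) rose. Of 13 members 6 rose and 4 (1 to 4) fell.

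Ribosome biogenesis and MYC genes fell with WT (median -0.32, adjusted p = 1.14e-09, adjusted p = 0.139 with an estimated correlation), among them the polyamine enzymes SRM (-0.96) and ODC1 (-0.66). Of 20 members 15 fell, or 17 adjusted over the list alone. TGF-beta targets fell (median -0.50, adjusted p = 1.37e-07, adjusted p = 0.139 with an estimated correlation), with PMEPA1 (-1.74) and ID1 (-0.95). Of 16 members 1 (0 to 1) rose and 9 fell, or 1 and 10 adjusted over the list alone. YAP/TEAD targets fell (median -0.39, adjusted p = 9.23e-05, adjusted p = 0.164 with an estimated correlation), such as the matricellular CYR61 (-1.90) and ANKRD1 (-1.62). Of 17 members 1 (1 to 2) rose and 9 fell, or 4 and 9 adjusted over the list alone. NOTCH pathway genes fell (median -0.44, adjusted p = 0.000117, adjusted p = 0.164 with an estimated correlation), with the ligand JAG1 (-1.35) and the receptors NOTCH3 (-1.67) and NOTCH1 (-0.80). Of 12 members 1 (0 to 1) rose and 8 (4 to 7) fell, or 2 and 8 adjusted over the list alone. Stress keratins and alarmins fell (median -0.67, adjusted p = 0.000192, adjusted p = 0.250 with an estimated correlation): KRT6A (-0.66), KRT16 (-1.40) and S100A9 (-1.24), of which the keratins have close paralogs. Of 9 members 5 fell, or 6 adjusted over the list alone. ATF4 and unfolded protein response genes fell (median -0.22, adjusted p = 0.00822, adjusted p = 0.262 with an estimated correlation), including ATF4 (-0.45) itself and the cystine transporter SLC7A11 (-0.41), although the stress gene DDIT4 (0.45) rose. Of 22 members 2 (1 to 3) rose and 10 (4 to 10) fell. Heat shock genes fell (median -0.22, adjusted p = 0.0325, adjusted p = 0.342 with an estimated correlation), such as the chaperone HSP90AA1 (-0.43), and the list lost its call without WT A (0.0916). Of 13 members 1 (0 to 2) rose and 7 (4 to 7) fell, or 1 and 8 adjusted over the list alone.

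Lists that did not pass with WT included the squamous transcription factors (median -0.08, adjusted p = 0.979), where TRIM29 (0.67) rose and RUNX1 (-0.86) fell. Of 23 members 6 rose and 6 (3 to 6) fell. Epithelial junction genes (median -0.19, adjusted p = 0.0797) parted into CLDN4 (-0.97), which fell, and the desmosomal PKP1 (0.62) and CLDN1 (0.72), which rose. Of 24 members 4 rose and 10 (6 to 9) fell. Among mesenchymal genes (median -0.31, adjusted p = 0.0786) N-cadherin, CDH2 (-1.36), and the smooth muscle protein TAGLN (-1.77) fell. Of 13 members 2 (0 to 2) rose and 5 (3 to 5) fell, or 2 and 6 adjusted over the list alone. G1/S genes did not pass (median -0.03, adjusted p = 0.714). Of 26 members 1 (0 to 1) rose and 2 (0 to 3) fell, or 0 and 1 adjusted over the list alone. Each of the calls was lost without some library, as CDC45 (-0.48) was without empty vector B (0.308), WT A (0.0644) and WT B (0.0707). Interferon response genes (median 0.20, adjusted p = 0.389) held BST2 (-1.76), tetherin, lost as a call without empty vector A (0.0526) and WT A (0.0907). Of 17 members 1 (0 to 1) rose and 1 (0 to 2) fell. In the cytokine list (median -0.19, adjusted p = 0.0628) the chemokine IL8 (-1.57), PTGS2 (-0.87) and TNFAIP3 (-0.76), an NF-kB inhibitor, fell. Of 14 members 4 fell, or 1 rose and 5 fell adjusted over the list alone. Among EGFR ligands and receptors (median 0.01, adjusted p = 0.967, mean -0.04, a downward test) the receptor EGFR (0.61) rose. Of 7 members 1 rose and 2 (1 to 2) fell, or 2 and 2 adjusted over the list alone. MAPK genes (median -0.06, adjusted p = 0.679) held DUSP6 (0.88) and ETV4 (0.73), which rose, and FOSL1 (-1.13), which fell. Of 20 members 4 (2 to 5) rose and 7 (4 to 7) fell, or 6 and 8 adjusted over the list alone.

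Further lists that did not pass with WT were KLF and SP factors (median 0.03, adjusted p = 0.265), where KLF13 (1.10) rose, and p53 targets (median -0.16, adjusted p = 0.582, mean 0.01, a downward test), where BTG2 (1.05) rose and GADD45A (-0.89) fell. Of 15 KLF and SP factors 4 (1 to 3) rose and 2 (0 to 2) fell. Of 21 p53 targets 4 (2 to 4) rose and 6 (1 to 5) fell. Glycolysis and hypoxia genes (median 0.25, adjusted p = 0.127) held the hypoxia-induced NDRG1 (1.86) and the glucose transporter SLC2A1 (0.79). Of 18 members 9 (5 to 9) rose and 4 fell, or 9 and 5 adjusted over the list alone. WNT targets (median -0.31, adjusted p = 0.0785) held DKK1 (-0.99) and the ubiquitin ligase RNF43 (-0.46). Of 7 members 3 fell. NRF2 targets (median -0.06, adjusted p = 0.128) held the reductase AKR1B10 (-0.98), which fell. Of 20 members 5 (3 to 6) rose and 7 fell, or 5 and 8 adjusted over the list alone. Intestinal epithelium genes (median 0.16, adjusted p = 0.187, mean -0.03, an upward test) included KRT8 (0.38). Of 8 members 3 rose, or 3 rose and 1 fell adjusted over the list alone. Nuclear oxidative phosphorylation genes (median 0.05, adjusted p = 0.505) and mitochondrially encoded genes (median 0.09, adjusted p = 0.212), with MT-ATP8 (0.34) and MT-ATP6 (0.22), did not pass. Of 24 nuclear oxidative phosphorylation genes 2 (0 to 2) rose, or 1 adjusted over the list alone. Of 13 mitochondrially encoded genes 2 (2 to 4) rose and 1 (0 to 1) fell, or 4 and 1 adjusted over the list alone. The lung lineage, histone and other-cell-type lists had under 5 genes tested in HCC95 and were not tested as lists. In them NKX2-1 (1.51), a lung lineage factor, rose, a call lost without empty vector A (0.118), empty vector B (0.162), WT A (0.0824) and WT B (0.321). Of the markers of fibroblasts, endothelium and immune cells COL6A1 (0.72) rose and CD68 (-0.45) fell, while VWF (0.25) was not called. Of 4 histone genes 0 (0 to 1) were called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05.

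In HCC95, NRF2, intestinal epithelium (8 of 22 tested), cholesterol synthesis and mitotic genes were higher with E419Q than with the empty vector. TGF-beta, NOTCH, ribosome biogenesis and stress keratin genes were lower. These calls were also lost with an estimated correlation. PRELP, a matrix proteoglycan, was at least 25.5-fold higher (62 counts against 0), NXF3 at least 15.6-fold higher (38 counts against 0), and sclerostin, SOST, a WNT antagonist, had 138 counts against 3 (56.7-fold, 95% counting interval 18.99 to 278). The floor for these bounds was 3 counts over the group. Filaggrin, FLG (4.40), a protein of the cornified layer, rose with a wide spread (16.8 ± 13.3 against 0.655 ± 0.927 CPM), and the integrin gene ITGB7 had 36 counts against 2 (22.2-fold, 95% counting interval 5.71 to 190.1). SCUBE3 (3.99), COL4A4 (3.99) (15.9-fold), and CLSTN2 (3.82) completed the 8 largest rises. OLFM4 had 1 count against 167 (136-fold, 95% counting interval 24.00 to 5387), and ZNF750, a transcription factor of epidermal differentiation, 2 against 52 (21.1-fold, 95% counting interval 5.56 to 179). MMP7 (-3.87) was 14.6-fold lower, CRYAB (-3.41), a small heat shock protein, 10.6-fold, and IL7R (-3.20) 9.19-fold. SPRR2A, a cornified envelope gene with close paralogs, had 3 counts against 40 (10.8-fold, 95% counting interval 3.45 to 54.7), and EMILIN2 (-3.27) fell. LGR5 (-3.19) fell too, a call lost without empty vector A (0.0834).

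Of the 12933 genes, 1340 rose and 1397 fell with E419Q against the empty vector (21.2%; 336 and 198 by at least 2-fold). DESeq2 called 573 and 596. Without E419Q A the edgeR counts were 862 and 899, and without E419Q B 822 and 804. Of 29 lists, 10 passed camera's test, 4 upward and 6 downward, and 0 with an estimated correlation (lowest adjusted p = 0.107), where 5 had an unadjusted p under 0.05; fry called 8.

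Cholesterol synthesis genes rose with E419Q (median 0.31, adjusted p = 0.000180, adjusted p = 0.602 with an estimated correlation), such as FDPS (0.71) and MVD (0.61). Of 23 members 10 (4 to 10) rose, or 11 adjusted over the list alone. NRF2 targets rose (median 0.14, adjusted p = 0.00361, adjusted p = 0.561 with an estimated correlation), with the reductase AKR1C1 (0.89), which has close paralogs, glutathione peroxidase GPX2 (0.63) and malic enzyme ME1 (0.53). Of 20 members 9 (5 to 9) rose and 1 (0 to 2) fell, or 10 and 2 adjusted over the list alone. Intestinal epithelium genes rose (median 0.45, adjusted p = 0.00483, adjusted p = 0.387 with an estimated correlation), among them KRT8 (0.94), KRT18 (0.83) and AGR2 (2.26), a disulfide isomerase of mucus-secreting cells. Of 8 members 4 rose and 1 (0 to 1) fell, or 4 and 2 adjusted over the list alone. G2/M genes rose (median 0.21, adjusted p = 0.00485, adjusted p = 0.561 with an estimated correlation), such as TOP2A (0.37) and NUSAP1 (0.39), while MYBL2 (-0.54) fell. Of 26 members 9 (2 to 7) rose and 1 fell, or 12 and 1 adjusted over the list alone. TGF-beta targets fell (median -0.78, adjusted p = 7.36e-09, adjusted p = 0.107 with an estimated correlation), with PMEPA1 (-1.41) and ID1 (-0.86). Of 16 members 12 fell, or 14 adjusted over the list alone. Ribosome biogenesis and MYC genes fell (median -0.30, adjusted p = 5.35e-09, adjusted p = 0.107 with an estimated correlation), such as SRM (-0.91), ODC1 (-0.55) and DKC1 (-0.49). Of 20 members 13 fell. ATF4 and unfolded protein response genes fell (median -0.33, adjusted p = 0.000128, adjusted p = 0.260 with an estimated correlation), including ATF4 (-0.60) and ASNS (-0.65), asparagine synthetase. Of 22 members 8 fell, or 10 adjusted over the list alone. NOTCH pathway genes fell (median -0.60, adjusted p = 0.00139, adjusted p = 0.260 with an estimated correlation), with JAG1 (-1.14), NOTCH3 (-1.55) and NOTCH1 (-0.85). Of 12 members 2 rose and 7 fell, or 2 and 9 adjusted over the list alone. Stress keratins and alarmins fell (median -1.16, adjusted p = 0.00379, adjusted p = 0.387 with an estimated correlation), such as KRT16 (-2.48) and S100A9 (-1.33). Of 9 members 2 rose and 7 fell. YAP/TEAD targets fell (median -0.20, adjusted p = 0.00683, adjusted p = 0.270 with an estimated correlation), with FJX1 (-1.05), CYR61 (-1.52) and tissue factor, F3 (-1.12). Of 17 members 2 rose and 7 fell.

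Other lists did not pass with E419Q. Basal squamous genes went both ways (median 0.19, adjusted p = 0.205): KRT15 (2.14) and the nerve growth factor receptor NGFR (2.02) rose and KRT17 (-1.78) fell. Of 20 members 9 rose and 6 fell, or 10 and 6 adjusted over the list alone. Squamous differentiation genes (median -0.24, adjusted p = 0.231) included KRT4 (-2.41) and KRT13 (-0.56), which fell, and PPL (0.83), which rose; the list's median was unchanged with SPRR1A, at 0 counts with E419Q, set to its bound. Of 13 members 3 rose and 6 fell. Squamous transcription factors (median 0.02, adjusted p = 0.844, mean -0.20, an upward test) held FOXE1 (1.38) and SOX2 (0.96), which rose, and EHF (-0.86), which fell. Of 23 members 7 rose and 6 fell, or 7 and 7 adjusted over the list alone. Epithelial junction genes were balanced (median -0.04, adjusted p = 0.708), with CGN (1.55), cingulin of tight junctions, up and CLDN4 (-0.70) down. Of 24 members 9 (5 to 9) rose and 9 (5 to 9) fell, or 10 and 10 adjusted over the list alone. For mesenchymal genes (median 0.06, adjusted p = 0.844, mean -0.11, a downward test) SPARC (0.78) rose and CDH2 (-1.30) fell. Of 13 members 3 (1 to 4) rose and 3 fell. G1/S genes (median -0.08, adjusted p = 0.358) and interferon genes (median 0.16, adjusted p = 0.448) did not pass. Of 26 G1/S genes 2 (0 to 2) rose and 1 (0 to 3) fell. Of 17 interferon genes 1 (0 to 1) rose. In the cytokine list (median -0.14, adjusted p = 0.708) PTGS2 (-2.55) fell and TNFAIP2 (0.63) rose. Of 14 members 3 (1 to 2) rose and 2 fell, or 4 and 2 adjusted over the list alone.

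EGFR ligands and receptors (median -0.12, adjusted p = 0.708) held ERBB2 (0.79), which rose, and the ligand TGFA (-1.32), which fell. Of 7 members 2 (1 to 2) rose and 2 fell. MAPK genes (median -0.13, adjusted p = 0.947, mean 0.14, an upward test) held ETV4 (1.71) and DUSP6 (0.96), both raised. Of 20 members 5 (3 to 6) rose and 6 fell, or 6 and 6 adjusted over the list alone. KLF and SP factors (median -0.18, adjusted p = 0.466) again included KLF13 (0.64). Of 15 members 1 rose and 3 (1 to 3) fell, or 2 and 4 adjusted over the list alone. Literature KLF5 targets (median -0.09, adjusted p = 0.636) held FGFBP1 (0.47), raised, and CDKN1A (-0.79), lowered. Of 12 members 3 rose and 5 (3 to 5) fell, or 4 and 5 adjusted over the list alone. For p53 targets (median -0.09, adjusted p = 0.467) DDB2 (0.83) rose and GADD45A (-0.56) fell. Of 21 members 3 rose and 6 (3 to 5) fell, or 4 and 7 adjusted over the list alone. Glycolysis and hypoxia genes (median -0.11, adjusted p = 0.5999, mean 0.01, a downward test) held NDRG1 (1.21), raised, and the enolase ENO1 (-0.41), lowered. Of 18 members 4 rose and 7 (3 to 7) fell, or 5 and 8 adjusted over the list alone. Heat shock genes (median -0.10, adjusted p = 0.573, mean 0.04, a downward test) included BAG3 (0.66), raised. Of 13 members 2 rose and 4 (2 to 4) fell. WNT targets (median -0.17, adjusted p = 0.231) and ribosomal proteins (median 0.05, adjusted p = 0.272) did not pass. Of 7 WNT targets 1 (0 to 1) rose and 3 (1 to 3) fell. Of 28 ribosomal proteins 5 (1 to 4) rose and 2 (1 to 3) fell, or 7 and 2 adjusted over the list alone. Mitochondrially encoded genes (median 0.11, adjusted p = 0.0921) held MT-ATP6 (0.25). Of 13 members 5 (1 to 4) rose, or 6 adjusted over the list alone. Of the 24 nuclear oxidative phosphorylation genes 0 (0 to 1) were called by edgeR, DESeq2 or limma-voom and 4 had an unadjusted p under 0.05 (median 0.04, adjusted p = 0.636, 0 adjusted over the list alone). Of the lists too short for a test, the lung lineage list held FOXA1 (-0.86), which fell, and FOXA2 (1.99), which rose, a call lost without E419Q A (0.186). Of its 4 members 1 (0 to 2) rose and 1 fell, or 2 and 1 adjusted over the list alone. Of the markers of other cell types VWF (1.19) and COL6A1 (0.98) rose and CD68 (-0.43) fell. Of 4 histone genes 0 were called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05.

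The changes made by WT and by E419Q against the empty vector had a Pearson r of 0.65 across genes, which are not independent replicates. Unchanged groups set against the same controls gave a mean r of 0.47 over 50 simulations, and the observed covariance was 0.146 against a simulated 0.0234, a difference of 0.123. Both forms raised 692 genes, where independent lists would share 144, and both lowered 916 genes, where independent lists would share 169. The 2 control libraries were not split between the comparisons, so part of the excess may come from the shared controls. The r was 0.589 without E419Q B, 0.598 without WT A and 0.706 without empty vector B.

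By list calls lost with an estimated correlation, intestinal epithelium (8 of 22 tested) and NRF2 genes were higher with E419Q than WT. Basal squamous, squamous differentiation, cholesterol and glycolysis genes were lower. The largest differences upward were EIF3CL (753 counts against 3, 289-fold, 95% counting interval 98.5 to 1404), whose reads overlap those of EIF3C, RAB43, a small GTPase with close paralogs (at least 17.3-fold higher, 45 counts against 0), and NXF3 (at least 14.6-fold higher, 38 against 0). SOST had 138 counts against 3 (52.96-fold, 95% counting interval 17.7 to 260.0) and DAAM2 40 against 1 (46.1-fold, 95% counting interval 7.805 to 1864). PRELP had 62 against 2 (35.7-fold, 95% counting interval 9.47 to 301) and the receptor kinase gene ROS1 33 against 2 (19.00-fold, 95% counting interval 4.86 to 163). SERPINB3 (3.74), the squamous cell carcinoma antigen with a close paralog, was 13.4-fold higher. Downward, KRT4 was 12.5-fold lower (-3.64, 6.23 ± 2.87 against 79.3 ± 6.09 CPM, edgeR adjusted p = 4.48e-11) and MMP10 (-2.96) 7.77-fold lower. IGFL1 (-3.05), the growth hormone receptor GHR (-3.03) and the ectodysplasin receptor EDAR (-2.63) were lower as well. Calbindin, CALB1 (-3.09), lost its call without E419Q B (0.05003), LOXL4 (-2.75) without E419Q A (0.106) and WT A (0.0683), and RP11-1035H13.3 (-2.63) without E419Q A (0.0610) and WT A (0.113).

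Of the 12933 genes, 570 were higher and 464 lower with E419Q than with WT (7.995%; 144 and 99 by at least 2-fold), and DESeq2 called 270 and 197. The edgeR counts were 348 and 249 without E419Q A, 351 and 256 without E419Q B, and 341 and 286 without WT B, and without WT A 254 were lower. By the direct test 339 genes stood above both other groups and 187 below both with E419Q, whereas 246 stood above both and 176 below both with WT. Of the genes raised by both forms, 567 showed no called difference between them. Of 29 lists, 10 passed camera's test, 3 upward and 7 downward, and 0 with an estimated correlation (lowest adjusted p = 0.264), where 5 had an unadjusted p under 0.05; fry called 5.

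NRF2 targets were higher with E419Q than with WT (median 0.25, adjusted p = 5.02e-11, adjusted p = 0.264 with an estimated correlation), including AKR1B10 (0.86), AKR1C1 (0.77) and GPX2 (0.77). Of 20 members 11 (7 to 11) were higher, or 13 adjusted over the list alone. Intestinal epithelium genes were higher (median 0.17, adjusted p = 0.000428, adjusted p = 0.277 with an estimated correlation), with AGR2 (1.47), KRT18 (0.73) and KRT8 (0.56). Of 8 members 3 were higher, or 4 adjusted over the list alone. Heat shock genes were higher (median 0.12, adjusted p = 0.01002, adjusted p = 0.376 with an estimated correlation), such as HSPA1B (0.43), which has a near-identical copy, and the list lost its call without WT A (0.174). Of 13 members 2 were higher. Cholesterol synthesis genes were lower (median -0.37, adjusted p = 2.69e-10, adjusted p = 0.376 with an estimated correlation), with INSIG1 (-0.47) and LSS (-0.44). Of 23 members 1 (0 to 1) was higher and 14 (6 to 14) lower, or 2 and 16 adjusted over the list alone. Literature KLF5 targets were lower (median -0.28, adjusted p = 3.35e-07, adjusted p = 0.264 with an estimated correlation), such as FGFBP1 (-0.89). Of 12 members 8 (2 to 8) were lower, or 9 adjusted over the list alone. Basal squamous genes were lower (median -0.30, adjusted p = 1.17e-06, adjusted p = 0.264 with an estimated correlation), with KRT17 (-2.15) down and NGFR (1.68) and KRT15 (0.92) up. Of 20 members 3 were higher and 11 (7 to 11) lower, or 3 and 12 adjusted over the list alone. Squamous differentiation genes were lower (median -0.83, adjusted p = 5.38e-05, adjusted p = 0.264 with an estimated correlation), with the keratins KRT13 (-1.18) and KRT4, and the median stayed at -0.83 with SPRR1A at its bound. Of 13 members 1 (0 to 1) was higher and 3 lower, or 1 and 4 adjusted over the list alone. Glycolysis and hypoxia genes were lower (median -0.22, adjusted p = 0.000408, adjusted p = 0.371 with an estimated correlation), such as ALDOC (-0.69), VEGFA (-0.67) and NDRG1 (-0.65). Of 18 members 2 were higher and 7 (3 to 7) lower, or 2 and 11 adjusted over the list alone. KLF and SP factors were lower (median -0.16, adjusted p = 0.00205, adjusted p = 0.264 with an estimated correlation), with KLF6 (-1.10), a paralog of KLF5. Of 15 members 3 (1 to 3) were lower. Ribosomal proteins were slightly lower (median -0.09, adjusted p = 3.34e-06, adjusted p = 0.475 with an estimated correlation). The call of RPLP0 (-0.19) was lost without E419Q A (0.109), E419Q B (0.0819), WT A (0.107) and WT B (0.0783). Of 28 members 3 (0 to 7) were lower, or 7 adjusted over the list alone.

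Lists that did not pass between E419Q and WT still held genes that differed. Squamous transcription factors (median -0.26, adjusted p = 0.801) held SOX2 (1.17) and FOXE1 (0.87), higher, and TP63 (-0.53), lower. Of 23 members 5 (3 to 6) were higher and 5 (3 to 5) lower, or 6 and 6 adjusted over the list alone. Epithelial junction genes (median 0.11, adjusted p = 0.260) held CGN (2.64) and CDH1 (0.66), higher, and the desmosomal cadherin DSG3 (-1.04), lower. Of 24 members 5 were higher and 5 (3 to 5) lower, or 6 and 5 adjusted over the list alone. Mesenchymal genes (median 0.15, adjusted p = 0.174) held SPARC (1.09) and the lysyl oxidase LOX (2.001), both higher. Of 13 members 3 were higher and 2 (0 to 2) lower. In the cytokine list (median 0.28, adjusted p = 0.184) PTGS2 (-1.68) was lower. Of 14 members 5 (1 to 4) were higher and 1 lower, or 6 and 1 adjusted over the list alone. EGFR ligands and receptors (median -0.20, adjusted p = 0.616) held EGFR (-0.72), lower, and ERBB2 (0.60), higher. Of 7 members 2 (1 to 2) were higher and 3 (1 to 3) lower. MAPK genes (median -0.06, adjusted p = 0.481, mean 0.14, an upward test) held the feedback inhibitor SPRY2 (1.43) and ETV4 (0.98), both higher. Of 20 members 5 (3 to 5) were higher and 1 (0 to 2) lower, or 5 and 3 adjusted over the list alone. Stress keratins and alarmins (median -0.09, adjusted p = 0.836, mean 0.29, an upward test) held LCN2 (0.86). Of 9 members 2 were higher and 1 (0 to 1) lower. For YAP/TEAD targets (median -0.01, adjusted p = 0.358, mean 0.10, an upward test) ANKRD1 (1.42) was higher. Of 17 members 4 (1 to 6) were higher and 1 (0 to 1) lower, or 6 and 1 adjusted over the list alone.

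TGF-beta targets (median -0.03, adjusted p = 0.821, an upward test) did not pass, and NOTCH pathway genes (median 0.04, adjusted p = 0.542) held HEY1 (1.52). Of 16 TGF-beta targets 1 (1 to 3) was higher and 1 lower, or 3 and 1 adjusted over the list alone. Of 12 NOTCH pathway genes 3 (1 to 3) were higher and 1 (0 to 1) lower. In the p53 list (median 0.04, adjusted p = 0.739, mean -0.13, a downward test) BTG2 (-0.56) lost its call without E419Q A (0.268) and WT A (0.138) and CDKN1A (-0.46) without E419Q A (0.0532), E419Q B (0.387), WT A (0.169) and WT B (0.145). Of 21 members 3 (0 to 3) were lower. BBC3, a pro-apoptotic gene with 3 counts against 24 (6.95-fold, 95% counting interval 2.11 to 36.05), lost its call without E419Q A (0.103), E419Q B (0.228) and WT B (0.0788). In the G2/M list (median -0.10, adjusted p = 0.0540) the proliferation marker MKI67 (-0.19) lost its call without E419Q A (0.377), E419Q B (0.0602), WT A (0.287) and WT B (0.109). Of 26 members 1 (0 to 1) was lower, or 0 adjusted over the list alone. ATF4 and unfolded protein response genes (median -0.09, adjusted p = 0.0672) held ATF3 (-1.47), a stress-induced factor. Of 22 members 1 (0 to 1) was higher and 5 (3 to 5) lower. Lists with 0 members called by edgeR, and also 0 by DESeq2 or limma-voom and 0 adjusted over the list alone, were G1/S (median -0.01, adjusted p = 0.481), interferon response (median -0.0002, adjusted p = 0.837), WNT targets (median 0.14, adjusted p = 0.616), ribosome biogenesis (median 0.05, adjusted p = 0.801), nuclear oxidative phosphorylation (median -0.03, adjusted p = 0.836) and mitochondrially encoded genes (median 0.03, adjusted p = 0.481). Their members with an unadjusted p under 0.05 numbered 5, 1, 1, 2, 2 and 1. With a library left out at most 1 ribosome biogenesis and 1 mitochondrially encoded gene were called. Of the lists too short for a test, the lung lineage list held FOXA1 (-0.66), lost as a call without E419Q A (0.173), E419Q B (0.125), WT A (0.117) and WT B (0.145). Of its 4 members 1 (0 to 1) was lower, or 2 higher and 2 lower adjusted over the list alone. The markers of other cell types held VWF (0.94), lost without WT B (0.0636). Of 3 members 1 (0 to 1) was higher, or 2 adjusted over the list alone. Of 4 histone genes 0 were called by edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05.

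**Figure D3:**
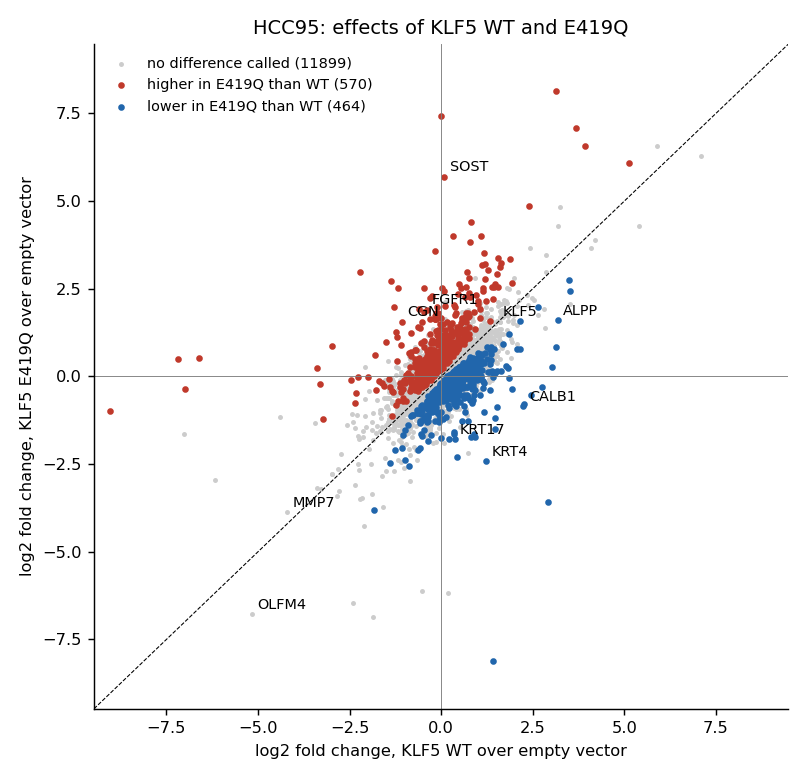
Log2 fold change over the empty vector with WT (horizontal axis) and with E419Q (vertical axis) for the 12933 genes tested in HCC95; the dashed line marks equal change, red points are the 570 genes higher and blue points the 464 genes lower with E419Q than with WT. KLF5 lies near the dashed line (1.52 and 1.58), and KRT4 (1.23 and -2.41) far under it.

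Both cell lines shared 12432 tested genes, which allowed the changes after silencing to be set beside those after overexpression. Across these genes the fold changes were nearly uncorrelated (Pearson r -0.04 with WT and 0.03 with E419Q, Spearman rho 0.03 and 0.08; genes are not independent replicates). By Fisher's exact test, 217 genes were lowered by siKLF5 and raised by WT (176 expected, odds ratio 1.32, p = 0.000611, adjusted p = 0.00105 over 24 such tests), and within classes of mean expression the odds ratio was 1.05 (Mantel-Haenszel p = 0.577). With at least a 2-fold change 13 genes did so (3 expected, odds ratio 4.85, exact p = 9.66e-06, adjusted p = 1.93e-05). KLF5 itself, which the design lowered in BICR31 and raised in HCC95, was in both counts. The genes with the largest summed changes were ALPP (-2.47) in BICR31 and ALPP (3.18) in HCC95, PSAPL1 (-2.26 and 1.84), KRT4 (-2.80 and 1.23) and HTRA1, a secreted protease (-1.25 and 1.69). NID2 changed by -0.30 in BICR31 and had 35 counts against 3 in HCC95 (12.5-fold, 95% counting interval 3.93 to 63.4); its BICR31 call was lost without siKLF5 C (0.109) and siNC B (0.107). CALB1 (-2.54 and 2.24) lost its call in BICR31 without siNC B (0.0998) and in HCC95 without empty vector B (0.0848). TGM1 (-2.59 and 1.25) lost its HCC95 call without empty vector A (0.111), empty vector B (0.0665), WT A (0.0964) and WT B (0.141), and SLC47A2, a transporter (-3.36 and 0.65), its BICR31 call without siKLF5 A (0.0533), siNC A (0.110), siNC B (0.0919) and siNC C (0.0666).

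**Figure D4:**
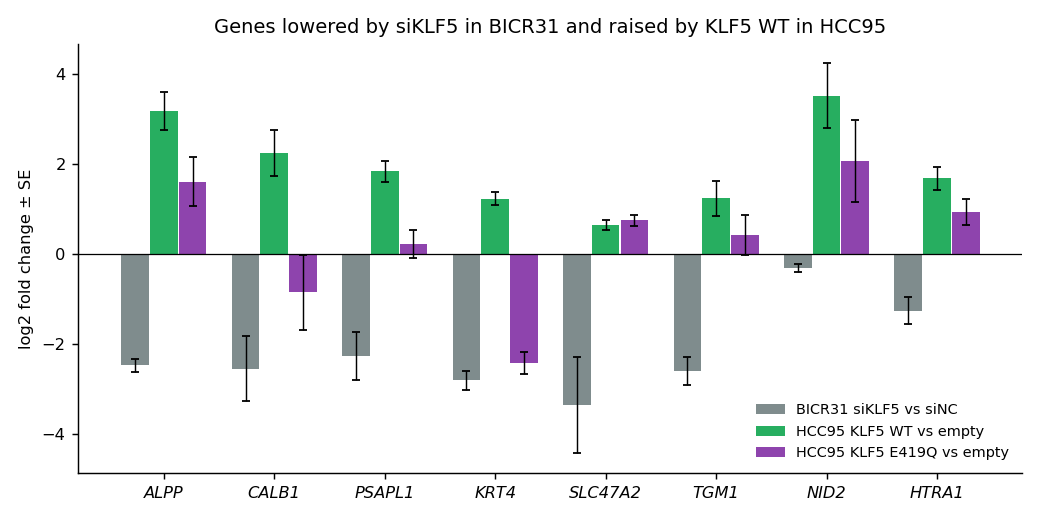
Log2 fold change with its SE (vertical axis) of 8 genes lowered by siKLF5 in BICR31 (grey) and raised by WT in HCC95 (green), with the E419Q change in HCC95 beside them (purple). KRT4 stands at -2.80, 1.23 and -2.41, and the fitted NID2 value in HCC95 rests on 3 counts in the empty vector libraries.

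Of the genes raised by siKLF5, 388 fell with WT (262 expected, odds ratio 1.79, adjusted exact p = 1.21e-17 over the 24 overlap tests), and among 2-fold changes 33 did (4.22 expected, odds ratio 10.7, adjusted exact p = 7.48e-20). With E419Q 312 fell (233 expected, odds ratio 1.51, adjusted exact p = 1.51e-08), with 1.13 within classes (Mantel-Haenszel p = 0.102). Among 2-fold changes 33 fell (4.898 expected, odds ratio 8.82, adjusted exact p = 7.93e-18). Those lowered by siKLF5 and raised by E419Q numbered 162 (167 expected, odds ratio 0.961, adjusted exact p = 0.693). This odds ratio was 3.33 among 2-fold changes (11 genes, adjusted exact p = 0.00138) and 0.761 within classes (Mantel-Haenszel p = 0.00368). Without 1 of siKLF5 B, siNC A or any HCC95 library it lay between 1.01 and 1.15. Genes also moved the same way after silencing and after overexpression. With WT 329 genes fell in both lines (199 expected, odds ratio 2.04, adjusted exact p = 4.42e-22), with 1.25 within classes (Mantel-Haenszel p = 0.00236). A further 274 rose in both (232 expected, odds ratio 1.26, adjusted exact p = 0.00211), with 2.44 among 2-fold changes (16 genes, adjusted exact p = 0.00344). With E419Q 329 fell in both (177 expected, odds ratio 2.41, adjusted exact p = 1.81e-31), with 1.52 within classes (Mantel-Haenszel p = 2.17e-08) and 1.95 among 2-fold changes (4 genes, adjusted exact p = 0.174). A further 333 rose in both (219.7 expected, odds ratio 1.83, adjusted exact p = 1.17e-16), with 2.89 among 2-fold changes (22 genes, adjusted exact p = 6.03e-05).

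Of genes lower with E419Q than with WT, 114 were lowered by siKLF5 (58.0 expected, odds ratio 2.40, adjusted exact p = 8.23e-13) and 118 raised by it (76.2 expected, odds ratio 1.79, adjusted exact p = 1.04e-06). Of genes higher with E419Q than with WT, 198 were raised by siKLF5 (91.96 expected, odds ratio 3.01, adjusted exact p = 5.10e-28) and 61 lowered by it (69.9 expected, odds ratio 0.850, adjusted exact p = 0.277). Among 2-fold changes these odds ratios were, in the same order, 6.15 (6 genes), 2.54 (6 genes), 7.07 (20 genes) and 2.80 (4 genes). Their adjusted exact p were 0.00111, 0.0462, 5.19e-10 and 0.0701. Within classes, with no limit on size, the odds ratios were 1.65, 1.57, 2.77 and 0.625. As sets chosen on the BICR31 libraries, the 151 genes lowered at least 2-fold by siKLF5 were higher with WT by camera (33 rose and 15 fell, adjusted p = 0.0419; adjusted p = 0.0715 with an estimated correlation). This call was lost without E419Q A (0.0504), WT A (0.0544), siKLF5 A (0.0646), siKLF5 B (0.105), siKLF5 C (0.128), siNC A (0.145) or siNC B (0.109). The 352 raised genes gave 45 up and 75 down (camera adjusted p = 0.150, a downward test with a median of 0.001). With E419Q against the empty vector neither set was called (27 up and 22 down, 60 up and 59 down, camera adjusted p = 0.730 each), and the lowered set had a median of -0.05 in an upward test. The test of the lowered set turned downward without siKLF5 A (0.803), siNC A (0.616) or siNC B (0.949), and that of the raised set without empty vector B (0.987). Between E419Q and WT the lowered set was lower (11 up and 17 down, adjusted p = 0.0209; adjusted p = 0.0563 with an estimated correlation). The raised set was higher there (49 up and 21 down, adjusted p = 0.0209; adjusted p = 0.0776 with an estimated correlation). With no limit on size the lowered set pointed downward with WT (adjusted p = 0.123) and was lower with E419Q than with the empty vector (adjusted p = 0.00315), and neither set was called between E419Q and WT (adjusted p = 0.111 each).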

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

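The tests of the KLF5 transcript level, of the EIF3C and EIF3CL sum between E419Q and WT, of leucocyte markers and of the interferon list were chosen after the results they bear on were seen. By a direct edgeR test 1034 genes differed between E419Q and WT. Among them, 26 genes were raised by WT and lowered by E419Q against the empty vector, and 22 were lowered by WT and raised by E419Q. Of the genes named in HCC95 with such opposite calls, those higher with E419Q than with WT were CGN (log2 fold change 2.64), LOX (2.001), HEY1 (1.52), SPRY2 (1.43), SPARC (1.09) and CDH1 (0.66). Those lower with E419Q were KRT4 (-3.64), MMP10 (-2.96), KRT17 (-2.15), ATF3 (-1.47), KRT13 (-1.18) and DSG3 (-1.04).

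For the genes that differed between E419Q and WT, the KLF5 transcript argued against an unequal dose of at least 1.5-fold, since its fold was 1.04 (95% interval 0.910 to 1.19). With all libraries thinned to the lowest total 942 genes differed, and with a length trend removed 1019 did, which argues against depth or length as the whole cause. A candidate explanation is that the change in the zinc-finger region alters which genes KLF5 acts on, which mapping the DNA binding of both forms would test. KLF5 protein was not measured, and the labels do not say whether each HCC95 group was 1 transduced population, so a difference between populations stays open.

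EIF3CL stood at 225, 0.378 and 115 CPM with the empty vector, WT and E419Q, and its near-identical copy EIF3C at 526, 528 and 393 CPM. Their sum was 1.42 times as high with the empty vector (752 ± 14.0 CPM) as with WT (529 ± 7.56 CPM), which argues against shared reads as the whole cause of the fall with WT. Between E419Q (508 ± 8.28 CPM) and WT the ratio of the sums was 0.961, so the higher EIF3CL level with E419Q may come from reads assigned to one copy or the other. What changed the sum was not tested, and no biological explanation was tested.

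For the cytokine genes raised by siKLF5, the same 22 of the list were raised with the deposited, the median-ratio and the quantile scaling, which argues against the deposited scaling as the cause. The 7 leucocyte markers summed to 18.5 units with siKLF5 and 6.08 units with siNC, the most abundant being LYZ and PTPRC, or 0.0799% of the summed rise of the cytokine list (23219.6 units). This argues against leucocytes in the cultures. The interferon list had a median log2 fold change of 0.54, so a reaction of the cells to the siRNA itself and an effect of KLF5 loss cannot be told apart without a second siRNA, which is not in the design. KLF5 loss is the biological explanation that the design names, and it stays open.

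The 6 BICR31 libraries allow 10 splits into 3 and 3, too few for a share under 0.05: the real split gave 4097 genes with limma, 1 of the 10 splits gave as many, and the highest other gave 0 (5710 against 301 genes at an unadjusted p under 0.05; no other tool was run on the splits).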

How the results depend on the processing

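Tests added after the results were seen were edgeR on recovered BICR31 counts, overlaps within classes of mean expression, thinned libraries and length correction. KLF5 kept its direction and its side of the threshold under each alternative run in each comparison (without single libraries -1.47 to -1.34 for siKLF5, 1.44 to 1.59 for WT, 1.502 to 1.64 for E419Q and 0.03 to 0.09 between E419Q and WT). The counts of changed genes stayed within 1.5 times of those reported under other pseudocounts, filters and scalings, limma-voom, edgeR on recovered counts (2259 raised and 2163 lowered), thinning (516 and 426) and length correction (577 and 442). Of 396 results for named genes, 5356 of 5835 values under alternatives kept their call and 479 lost it. Of 51 results for gene lists, 66 of 459 values lost their call and 1 changed direction: the adjusted p of mitochondrially encoded genes was 5.04e-05 to 0.672 with a library left out, with the direction turned without siKLF5 A. The causes of the changes listed here were not tested, except that stricter size limits leave fewer genes and left-out libraries fewer samples.

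Limma without a trend called 1420 raised and 861 lowered genes in BICR31. With at least a 2-fold change the counts were 568 and 193 for siKLF5, 274 and 171 for WT, 336 and 198 for E419Q and 144 and 99 between E419Q and WT. DESeq2 called 511 and 626, 573 and 596, and 270 and 197 in the 3 HCC95 comparisons, in that order. With an estimated correlation camera called 3 lists up and 4 down in BICR31 and 0 in HCC95. Fry called 18 lists up in BICR31, 1 up for E419Q and 3 down between E419Q and WT.

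With a library left out, 1868 to 2222 genes rose and 1313 to 1412 fell for siKLF5, 785 to 1322 and 934 to 1471 for WT, 822 to 1255 and 804 to 1348 for E419Q, and 341 to 637 and 249 to 536 between E419Q and WT. A group left with a lone library was assumed to vary like the others. The correlation of the WT and E419Q changes was 0.589 to 0.706. The BICR31 lowered set in WT had an adjusted p of 0.0166 to 0.145 (0.0715 with an estimated correlation, 0.123 downward with no limit on size), and the raised set 0.0646 to 0.316. In E419Q the lowered set had 0.616 to 0.949, with a change of direction in 3 of 12 fits, and 0.00315 downward with no limit on size. The raised set had 0.616 to 0.987, with a change of direction without empty vector B. Between E419Q and WT the lowered set had 0.0563 with an estimated correlation and 0.111 with no limit on size, and the raised set 0.0776 and 0.111.

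Within classes the odds ratio of genes lowered by siKLF5 and raised by WT was 1.05, and of genes raised by siKLF5 and lowered by E419Q 1.13. For genes lowered by siKLF5 and raised by E419Q it was 0.761, or 3.33 among 2-fold changes and 0.917 to 1.15 with a library left out, where it changed direction in 8 of 12 fits. For genes lowered by siKLF5 and E419Q it was 1.95 among 2-fold changes. Within classes and among 2-fold changes the other overlaps kept their direction and call, except genes lowered by siKLF5 and higher with E419Q than with WT (2.80 among 2-fold changes, 0.625 within classes).

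The replicate letters did not pair the libraries: deviations of same-letter libraries correlated at -0.00165 to 0.0260 in BICR31 and -0.0342 to 0.0248 in HCC95. With the letter as a replicate block 2402 genes rose and 1674 fell for siKLF5, 1362 and 1538 for WT, 1306 and 1380 for E419Q, and 553 and 434 between E419Q and WT. Depth limits genes near 3 counts, and in simulated data 41.8% to 56.7% of 1.5-fold changes were called.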

Other observations

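The genes in this paragraph were chosen after their values were seen. Among the genes that WT lowered and E419Q raised against the empty vector were membrane proteins outside the gene lists (CPM, n = 2 per group; edgeR). FGFR1, a fibroblast growth factor receptor, stood at 368 ± 19.2 CPM with E419Q, 98.3 ± 4.56 CPM with the empty vector and 74.8 ± 2.09 CPM with WT, a log2 fold change of 2.30 between E419Q and WT (adjusted p = 9.35e-15). GPC4, a heparan sulfate proteoglycan, stood at 114 ± 4.15, 32.0 ± 0.439 and 22.9 ± 2.46 CPM (2.30, adjusted p = 3.35e-12). LRIG1, a negative regulator of growth factor receptors, stood at 191 ± 3.895, 65.6 ± 7.25 and 44.96 ± 1.21 CPM (2.09, adjusted p = 1.05e-12). No explanation of these differences was tested.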
